A study of Mus musculus with 6 samples.

How the data were processed

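Total RNA came from anti-PECAM bead-purified cerebellar endothelial cells of mice at postnatal day 16, of mixed sex and a mixed strain background, 3 Fz4-null and 3 wild-type preparations, per the labels. RNA was extracted with Trizol and RNeasy columns and biotin-labelled for Affymetrix 3' arrays, per the labels' protocols. The deposited values are log2 expression from RMA, per the submitters' processing notes, a method that corrects background, normalizes arrays to a common distribution and summarises each probe set. The RMA implementation and its version are not given in the sources used here. RMA compresses differences near background, so folds of dim genes can be understated. The labels do not say whether the preparations came from separate animals or pools, so p-values measure the spread between these samples.

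The table held 45101 probe sets, of which 64 Affymetrix controls were left out and 45037 were tested. Probe sets were named from the platform annotation, where 34945 carried 1 gene symbol, 932 several and 9160 none, and 34741 matched a gene of the RefSeq table of assembly GRCm38.p6 by identifier, with 0 symbols changed. Genes were named only from probe sets with 1 symbol, and a gene was read from its probe set with the highest mean over the 6 arrays, giving 18193 genes. A library depth does not apply to arrays. Arrays did not repeat one another, with at most 0.351% of probe sets at identical values in any pair.

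Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), with all 6 arrays, no covariate, 2 groups, two-sided tests and Benjamini-Hochberg adjustment over the 45037 probe sets at 0.05. Values are mean ± SD with n = 3 and log2 differences with their moderated SE. An exact permutation of 3 against 3 arrays cannot give a p below 0.1, so none was used for single genes. For gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01 on the 29 lists with at least 5 measured members and adjusted over the lists. None of its 12 calls held with an estimated correlation, while fry gave 2 for a shift in 1 direction and 4 for change in either direction. Neither fry test compares a list with other genes. List members were also adjusted over the list alone. Some members of the non-endothelial lists are expressed in endothelial cells too.

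The rule for named genes, set before the data were examined, took Fzd4, up to 12 higher and 12 lower genes with the largest difference among those past the threshold whose groups did not overlap, and up to 3 members per list past the threshold or otherwise the 1 with the lowest p. It gave 31 genes. Others were named after their values were seen.

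The labels number the replicates 1 to 3 in both genotypes. Deviations from the group means correlated across probe sets at 0.244, 0.303 and 0.574 for the same numbers, all above the minimum of 0.1 set for pairing. Unlike numbers also exceeded it, at 0.124 for null replicate 1 with wild-type replicate 2 and 0.262 for null replicate 2 with wild-type replicate 1. Deviations sum to 0 within a group, so the match of the arrays numbered 3 raises correlations among the rest. The criterion therefore cannot show that numbers 1 and 2 are pairs, and the block was fitted as an alternative only. Null replicate 1 correlated best with its own number, whereas null replicate 2 did so at 0.303 against 0.262 for wild-type replicate 1, which itself lay closer to null replicate 2 than to null replicate 1. The block leaves 2 residual degrees of freedom against 4.

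Limma and camera were tested on 10 simulated data sets that used the probe sets' wild-type means and moderated SDs with independent noise and 200 changed genes. At 45037 probe sets, limma recovered 4.71% of genes changed by log2 1, 77.4% at log2 2 and 98.9% at log2 4, and 5.11% of its calls were false. Camera found 100% of planted lists of 20 genes shifted by 0.5 and called 2.00% of random lists at an unadjusted p under 0.05. Correlated noise, as the real arrays show, was not simulated.

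Alternatives were quantile, median-centred and cyclic loess normalization, filters on dim probe sets (the median level, or log2 of 100), a variance trend with robust estimation, array weights, leaving out probe sets that can read several transcripts, the mean of a gene's probe sets, an unmoderated statistic, the replicate block, each array left out in turn, adjusted p of 0.01 and 0.1, and other list tests. Leaving out both arrays numbered 3, a batch term for them and the fenestrated list without Esm1 and Plvap were added after seeing the data. Figures were drawn with matplotlib.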

Results

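Gene expression was measured in endothelial cells taken from the cerebellum of mice at postnatal day 16, captured with magnetic beads against PECAM, a surface protein of endothelial cells. The mice either lacked Frizzled4 (the Fzd4 gene product, a receptor that carries Norrin and Wnt signals into endothelial cells) or were wild type. Each genotype had 3 preparations, and each was hybridised to 1 Affymetrix 3' expression array, giving 6 arrays. The comparison asked how the endothelial transcriptome differs after a lasting loss of Frizzled4 signalling. All values are log2 RMA expression, differences are Fz4-null minus wild type, and the number of arrays limits the precision. Array medians lay between 5.52 and 5.58.

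Fzd4, the targeted gene, was lower in all 3 null arrays. Its brightest probe set read 10.63 ± 0.37 (SD, n = 3) in wild type and 3.69 ± 0.56 in the null arrays. The fall was estimated at 6.94 (SE 0.34) on the log2 scale, with limma adjusted p = 0.00965. The null level lies about at the arrays' lower quartiles (3.46 to 3.64), so the fall may be understated. The other Fzd4 probe sets, both dimmer, read -4.95 (adjusted p = 0.0769) and -1.74 (adjusted p = 0.850). Which part of the gene was deleted is not given in the sources used here, so it is open whether each probe set lies inside it.

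Beside Fzd4, 3 named genes passed the threshold, all higher in the null arrays. Exoc3l2, which is related to an exocyst subunit, rose 22.1-fold, from 6.39 ± 0.40 to 10.86 ± 0.40 (log2 difference 4.47, SE 0.29, n = 3, adjusted p = 0.0189). Esm1, an endothelial proteoglycan secreted at sites of vessel growth, rose 15.0-fold, from 5.52 ± 0.16 to 9.43 ± 0.44 (log2 difference 3.91, SE 0.26, adjusted p = 0.0189). Fam167b rose 9.49-fold, from 5.38 ± 0.10 to 8.62 ± 0.29 (log2 difference 3.25, SE 0.21, adjusted p = 0.0189). The remaining probe set past the threshold is unnamed here and read 3.44 higher in the null arrays, from 3.16 in wild type, below the same quartiles (adjusted p = 0.0200). In all, 5 of 45037 probe sets and 4 of 18193 genes passed an adjusted p of 0.05, 3 higher and 1 lower, and all 4 differed at least 2-fold. With the replicate number as a block, 0 genes passed in limma, with adjusted p = 0.127 for Fzd4 and Esm1 and 0.247 for Exoc3l2 and Fam167b, and the unnamed probe set did not pass (0.314), while 1617 genes had an unadjusted p under 0.05 against 837 without the block. Leaving out 1 array left 0 to 2 genes past the threshold, namely Fzd4 without null replicate 1, Fzd4 and Plvap without wild-type replicate 3, and 0 genes without any of the other 4 (556 to 932 with an unadjusted limma p under 0.05). An unmoderated statistic called 0 genes, with 891 at an unadjusted p under 0.05, and a batch term for the arrays numbered 3 called Fzd4 alone.

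The genes next in rank were chosen after their values were seen, and none passed the threshold. Ddc, the enzyme that makes dopamine and serotonin from their precursors, read -2.03 (SE 0.18, adjusted p = 0.0810), while its other, dimmer probe set read higher in the null arrays. Ndnf, a secreted factor, read -2.64 (SE 0.24, adjusted p = 0.0834). The homeobox genes Hoxd8 (2.30) and Irx5 (2.15) and the phospholipid scramblase Plscr2 (2.01) each had an adjusted p of 0.107. Col8a2, a short-chain collagen, read -2.23 and F8, coagulation factor VIII, read 1.75, at the same adjusted p.

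**Figure D1:**
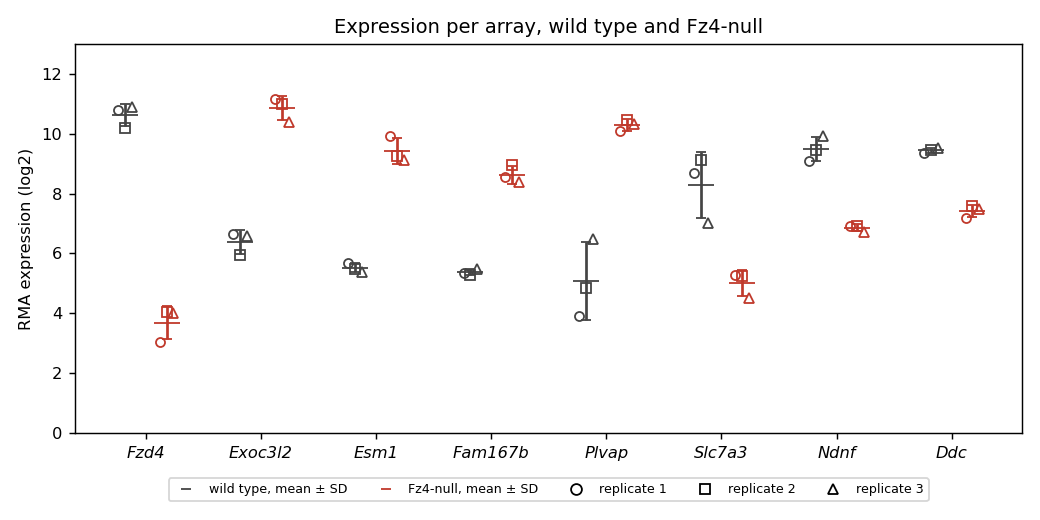
RMA expression (log2, vertical axis) of 8 genes on each of the 6 arrays, with wild type in grey and Fz4-null in red. Symbols give the replicate number and bars the mean ± SD of 3 arrays. Fzd4 is lower and Exoc3l2, Esm1 and Fam167b are higher in every null array.

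Endothelial genes typical of fenestrated or peripheral vessels rose as a group in the null arrays. Of 18 measured members, 1 passed over all probe sets (Esm1) and 8 passed when adjusted over the list alone, all 8 higher. Plvap, which forms the diaphragms of fenestrae, rose 37.1-fold, from 5.08 ± 1.31 to 10.29 ± 0.19 (SD, n = 3; log2 difference 5.21, SE 0.60, adjusted p = 0.126 over all probe sets and 0.000595 over the list alone). By replicate number Plvap differed by 6.18, 5.61 and 3.85. Its log2 difference was 5.92 without wild-type replicate 3 and 4.63 without wild-type replicate 1. By the list alone there were also rises in Cd300lg (2.52, SE 0.48), in the fatty acid and lipoprotein handling genes Fabp4 (1.95, SE 0.39) and Gpihbp1 (1.84, SE 0.36), and in the lipid phosphatases Plpp3 (1.21, SE 0.19) and Plpp1 (0.86, SE 0.21). The eighth, the Wnt agonist Rspo3, read 3.27 in wild type and 3.87 in the null arrays, where the arrays' lower quartiles were 3.46 to 3.64, so it is not shown to lie above background, and its other probe set read lower. The other 10 members did not pass, among them Cd36 (1.37), Emcn (0.41), Aqp1 (-0.50) and Car4 (-0.41). The list's median difference was 0.52, with camera adjusted p = 1.53e-10 at a preset correlation and adjusted p = 0.103 with an estimated correlation. Without null replicate 1 the median was 0.82. Fry, which asks whether a list's own genes move, gave adjusted p = 0.0147 for 1 direction. Without Esm1 and Plvap, left out after seeing the data, the list's median was 0.43, with 6 members past the list-alone threshold. The camera adjusted p at the preset correlation was then 1.65e-06. The Fabp4 value rests on a probe set that can read several transcripts, and without such probe sets Fabp4 was read from a dimmer one, at -0.12. Such probe sets also gave the values of Notum, Kcne3 and Ttr below.

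Blood-brain barrier transporter genes shifted lower as a group, by little at the median. Slc7a3, a cationic amino acid transporter, fell by 3.26 (SE 0.55), from 8.28 ± 1.11 to 5.02 ± 0.43 (SD, n = 3), with adjusted p = 0.465 over all probe sets and 0.0181 over the list alone. Slc7a3 read -3.89 without wild-type replicate 3 and -2.84 without wild-type replicate 2. It was the only 1 of 28 measured members to pass over the list alone, and 0 passed over all probe sets. The amino acid transporter Slc38a5 (-0.78), the organic anion transporter Slc22a8 (-0.92), the transferrin receptor Tfrc (-0.51), the lipid transporter Mfsd2a (-0.33) and the glucose transporter Slc2a1 (-0.05) did not pass. The median of the list was -0.14 (camera adjusted p = 0.000564, and adjusted p = 0.346 with an estimated correlation). Fry gave adjusted p = 0.198 for 1 direction and 0.0414 for change in either direction. With the replicate block 3 members passed over the list alone, Slc7a3, Slc22a8 and Slc5a6. Leaving out any array other than wild-type replicate 3 left 0 members past the list-alone threshold. The median read -0.23 without null replicate 1 and -0.09 without null replicate 2. Choroid plexus epithelium, which shares transporters such as Slc22a8, was lower on the same arrays, its list lying at -1.63, -1.23 and -1.49 on null replicates 1 to 3 against -0.31, -0.47 and -0.21 for the transporters. Without wild-type replicate 3, the array with the most choroid plexus signal, the transporter median was -0.20 (camera adjusted p = 0.0144).

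Canonical Wnt target and feedback genes were lower as a group. Over the list alone, 4 of 21 measured members passed, and 0 over all probe sets. The Wnt feedback inhibitors Notum and Nkd1 fell by 1.78 (SE 0.44) and 1.27 (SE 0.31), and the transcription factor Sp5 fell by 1.27 (SE 0.35). Lgr5, an R-spondin receptor, rose by 1.05 (SE 0.23) from a low level (4.03 ± 0.22, SD, n = 3), and its other probe set read lower in the null arrays. The targets Axin2 (-0.56), Apcdd1 (-0.32), Sox17 (0.13) and Lef1 (0.01) did not pass. The median was -0.20 (camera adjusted p = 0.0117, and adjusted p = 0.344 with an estimated correlation), and fry gave adjusted p = 0.0314. With the replicate block 5 members passed over the list alone, Sox9 (-0.65) being the addition. Leaving out 1 array left 0, 1 or 5 members past the list-alone threshold, 5 without wild-type replicate 1, 1 without null replicate 2 and 0 otherwise, and keeping only probe sets above the median level or above log2 of 100 left 2 and 0. The median read -0.35 without null replicate 1, -0.30 without null replicate 2 and -0.10 without null replicate 3. On null replicates 1 to 3 the list's mean lay at -0.32, -0.32 and -0.26 against the wild-type mean. Choroid plexus genes lay at -1.63, -1.23 and -1.49 on the same arrays, and platelet genes at -0.69, -0.46 and -0.26. Whether other cells in the preparations lowered the Wnt list was not tested.

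**Figure D2:**
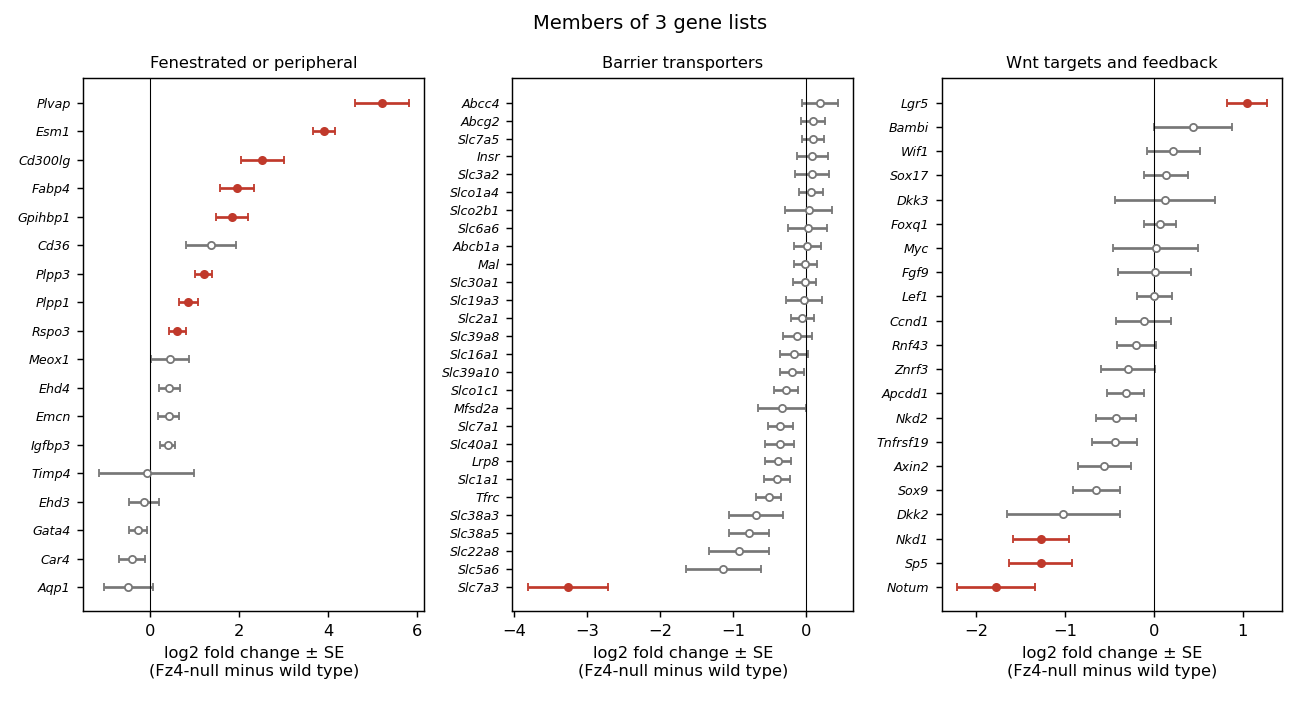
Log2 differences (Fz4-null minus wild type, horizontal axis, ± SE, 3 arrays per group) of the measured members of the fenestrated or peripheral, barrier transporter and Wnt target lists. Filled red points passed when adjusted over the list alone, 8 of 18, 1 of 28 and 4 of 21 members.

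Tip cell and sprouting genes shifted higher as a group, with 0 of 23 members past the threshold over all probe sets and 1 adjusted over the list alone. Esm1, which passed over all probe sets, was counted in the fenestrated list and is not among these 23. Kcne3, a potassium channel subunit, rose by 1.84 (SE 0.34). The median was 0.21 (camera adjusted p = 0.00103, and adjusted p = 0.552 with an estimated correlation), and fry for 1 direction gave adjusted p = 0.423. With the replicate block 6 members passed over the list alone, 5 of them not passing without it, namely Trp53i11 (1.05), Mmp14 (0.66), Ramp3 (1.46), Lamb1 (0.67) and Plaur (-0.72). Without wild-type replicate 3 the median was 0.36 and 3 members passed over the list alone, and without null replicate 1, null replicate 3, wild-type replicate 1 or wild-type replicate 2 the number was 0. The list's mean lay 0.40, 0.14 and 0.48 above the wild-type mean on null replicates 1 to 3, and that of pan-endothelial genes 0.27, 0.07 and 0.20, and whether higher endothelial purity raised the tip cell list was not tested.

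The remaining endothelial and signalling lists did not pass as groups with all 6 arrays and no block. Median differences were 0.03 for Wnt receptors and transducers (camera adjusted p = 0.977), 0.005 for tight and adherens junctions (0.926), 0.05 for caveolae (0.230), -0.06 for arterial (0.661), 0.01 for venous (0.468), 0.18 for basement membrane (0.177), 0.09 for TGF-beta and BMP (0.215), 0.03 for hypoxia (0.361), 0.009 for cell cycle (0.977) and 0.0002 for inflammation and interferon (0.949). The junction gene Cldn5, a main tight junction protein of brain endothelium, read 12.62 ± 0.24 in wild type and 12.60 ± 0.21 in the null arrays (SD, n = 3). Over the list alone, Egln3, an oxygen-sensing hydroxylase, rose by 1.18 (SE 0.23) in the hypoxia list and lost that call when null replicate 2 or 3 or any wild-type array was left out, and 0 members of the other 9 passed. With the replicate block the basement membrane list passed (camera adjusted p = 0.0239), and over the list alone the leukocyte adhesion receptor Sele (1.78) and Ctsc (-0.74) passed in the venous list, Sele in the inflammation list and Mmrn1 (-0.98) in the basement membrane list. Basement membrane genes also passed without null replicate 2 (median 0.28, camera adjusted p = 0.0457) and without wild-type replicate 3 (0.36, 0.0242). The list passed too without both arrays numbered 3 (0.14, 0.0370) and with a batch term for them. It did not pass without null replicate 1 (0.26, 0.188). Nor did it without null replicate 3 or wild-type replicates 1 and 2, with medians of 0.04, 0.09 and 0.08. With an estimated correlation and all 6 arrays, camera gave adjusted p = 0.782. TGF-beta and BMP genes passed without null replicate 3 (0.23, 0.0163) or wild-type replicate 1 (0.11, 0.0361), yet the median was 0.03 without null replicate 1 and -0.09 without wild-type replicate 3. Cell cycle genes passed without null replicate 2 (0.36, 0.000955) or wild-type replicate 3 (0.33, 0.0360), and their median lay between -0.21 and -0.12 without any other array. Members with the lowest p elsewhere were Fzd1 (-0.61), Jam3 (0.46), Cavin3 (0.60), Gkn3 (-1.29), Bmp6 (1.28) and Tyms (-0.42), none of which passed. For Wnt receptors, junctions, cell cycle and inflammation, the median was above 0 while camera pointed lower, and the mean was above 0 for cell cycle and below 0 for the other 3.

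Pan-endothelial genes were slightly higher in the null arrays, and the group medians of several other cell types were lower. The pan-endothelial median was 0.11 (25 members, 0 past any threshold, camera adjusted p = 0.00453, and adjusted p = 0.624 with an estimated correlation), with Clec14a at 1.00 (SE 0.24) and Pecam1 at 0.43 (SE 0.19). For the list, fry for 1 direction gave adjusted p = 0.381. Without null replicate 1 its median was 0.04 (adjusted p = 0.180), and without null replicate 2 it was 0.18. Choroid plexus epithelium genes had a median of -1.62 (camera adjusted p = 2.69e-08, and adjusted p = 0.517 with an estimated correlation), and fry for 1 direction gave adjusted p = 0.423. Of 12 members, 0 passed over all probe sets and 2 over the list alone, where the thyroid hormone carrier Ttr fell by 2.48 (SE 0.50) and the transcription factor Otx2 fell from 6.80 ± 0.78 to 5.30 ± 0.26 (SD, n = 3). With the replicate block 3 passed, Folr1 (-1.81) being the addition. Leaving out 1 array left 0 members without null replicate 1, 1 without null replicate 2 or 3, and 5, 6 and 3 without wild-type replicates 1, 2 and 3. Wild-type replicate 3 held the most choroid plexus signal, 1.34 above the wild-type mean, and without it the median was -0.87.

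Null replicate 1 stood apart in genes of non-endothelial cells. On that array the mean of the list lay below the wild-type mean by -2.45 for fibroblast and meningeal genes, -2.35 for microglia and macrophages, -1.68 for astrocytes and Bergmann glia and -1.28 for pericytes and smooth muscle. The median differences between groups were -0.87 (camera adjusted p = 0.000564), -0.62 (0.000564), -0.50 (0.00453) and -0.33 (0.0117), and without null replicate 1 they were -0.05, 0.10, 0.19 and 0.26, none past the threshold. They lay farther from 0 without null replicate 2 (-1.48 for fibroblast and -0.79 for astrocyte genes) and without null replicate 3 (-1.07 for microglia and -0.60 for mural genes). With an estimated correlation, adjusted p = 0.730 for each of these 4 lists. Purkinje cell genes (median -0.30, adjusted p = 0.0433, and adjusted p = 0.607 with an estimated correlation) passed only while null replicates 1 and 3 and wild-type replicate 3 were kept, with medians of -0.29, -0.31 and -0.23 and adjusted p = 0.329, 0.138 and 0.208 without each, and lost their call under quantile normalization, cyclic loess, a robust variance trend and array weights. Platelet genes had a median of -0.29 (adjusted p = 0.00326, and adjusted p = 0.344 with an estimated correlation). On all 6 arrays the mean of the platelet list (4.64 to 5.45) lay below the array medians, so its dimmer members may lie near background. Its member Pf4 differed by -3.57, -0.35 and -0.79 by replicate number. Without wild-type replicate 3 the astrocyte and mural medians were -0.27 and -0.19, neither past the threshold. In these 6 lists 0 members passed, either over all probe sets or adjusted over the list alone, and the lowest p values belonged to Fmod (-1.74), Mrc1 (-2.07), Hopx (-0.78), Tagln (-0.41), Foxp2 (-0.61) and Pf4 (-1.57).

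Granule neuron, interneuron, oligodendrocyte, red cell and leukocyte genes did not pass with all 6 arrays, with medians of -0.07 (camera adjusted p = 0.468), -0.08 (0.633), 0.04 (0.361), -0.12 (0.321) and -0.24 (0.177). Leukocyte genes passed without null replicate 3 (median -0.54, camera adjusted p = 0.000749), without wild-type replicate 1 (-0.27, 0.0365) and without both arrays numbered 3 (-0.40, 0.00540), but their median was 0.11 without null replicate 1 and -0.13 without wild-type replicate 2. Granule neuron genes passed without null replicate 3 (-0.32, 0.0230), while their median was 0.28 without null replicate 1 and 0.22 without wild-type replicate 3. The members of these 5 lists with the lowest p were Grin2c (-0.46), Tfap2a (0.98), Sox10 (-0.50), Slc4a1 (-0.81) and Ngp (-1.12), of which Grin2c and Tfap2a lay near the arrays' lower quartiles. Immediate early and heat shock genes had a median of 0.001 (0.949), with Hsph1 at -0.22, and sex-linked genes one of 0.07 (0.652), with Kdm5c at 0.15. The interneuron list's mean (0.01) and the oligodendrocyte list's mean (-0.14) had the opposite sign to their medians, and camera pointed lower for both. The stress list's median was above 0 while its mean (-0.004) and camera pointed lower.

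The arrays numbered 3 stood apart in both genotypes. The first principal component held 43.0% of the variance and separated these arrays (75.2 and 84.8) from the other 4 (-47.5 to -30.8). Their 3' to 5' log2 difference in the Gapdh control probe sets was 2.03 in null and 2.20 in wild type, against 0.87 to 1.07 on the other arrays, whereas for the beta-actin controls it was 1.18 and 1.14 against 0.94 to 1.08. With both left out, limma called 0 genes (1496 with an unadjusted p under 0.05), and the fenestrated list had a median of 0.53 (camera adjusted p = 1.08e-05) with 7 members past the list-alone threshold.

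**Figure D3:**
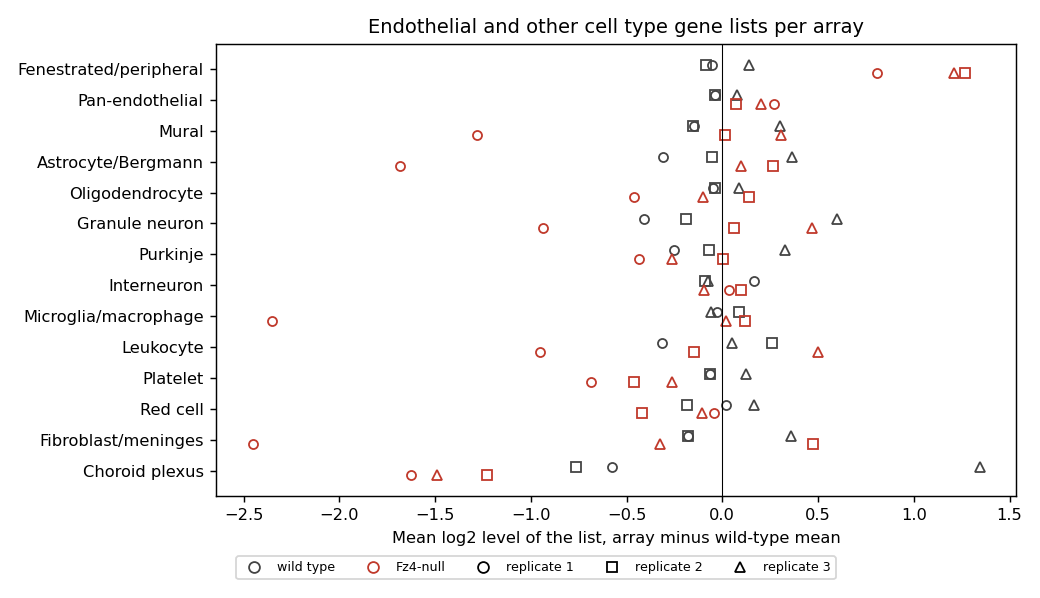
Mean log2 level of 14 gene lists on each array minus the wild-type mean (horizontal axis), with wild type in grey, Fz4-null in red and symbols for the replicate number. The fenestrated or peripheral list lies at 0.81 to 1.27 on the null arrays, and null replicate 1 lies at -2.45 for fibroblast and meningeal genes.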

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

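Depth on arrays is signal over background, which limits dim probe sets such as Lgr5. Quantile normalization, median centring, cyclic loess, the median-level filter, the trend with robust estimation and leaving out probe sets that can read several transcripts each called the same 4 genes, and both of the arrays numbered 3 left out, the batch term and the shortened fenestrated list were chosen after seeing the data. Above log2 of 100 the lower genes numbered 3 and the other cell type lists 4, and 4 such lists passed above the median level. Array weights called 12 genes (8 higher, 4 lower, 12 at least 2-fold), and the mean of probe sets 11 (8 higher, 3 lower, 11 at least 2-fold). The unmoderated statistic, the replicate block and leaving out both arrays numbered 3 called 0 genes, 0 higher, 0 lower and 0 at least 2-fold, with Fzd4 at -6.94, -6.94 and -6.96, with 891, 1617 and 1496 genes at an unadjusted p under 0.05 and fewer residual degrees of freedom in the last 2. The batch term and an adjusted p of 0.01 each called 1 gene, at least 2-fold, and 0 higher, and an adjusted p of 0.1 called 3 lower. Leaving out each array in turn gave 0 to 2 genes, 0 to 2 at least 2-fold, 0 to 1 higher, 0 to 1 lower, Fzd4 between -7.15 and -6.61, 6 to 14 lists and 2 to 8 lists of other cell types, with fewer arrays. In the same runs medians ranged from -0.60 to 0.26 for mural, -0.79 to 0.19 for astrocyte, -1.07 to 0.096 for microglia, -1.48 to -0.050 for fibroblast and -0.21 to 0.36 for cell cycle genes, the last passing without null replicate 2 or wild-type replicate 3. An estimated correlation called 0 lists, fry 2 for 1 direction and 4 for either, and 0 of other cell types in each. Fabp4 read -0.12 without probe sets that can read several transcripts. Where no construction shows it, the cause was not tested.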

Other observations

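Receptors and transducers of Wnt signals other than Fzd4 lay both above and below wild type. Fzd1 (-0.61, SE 0.20), Fzd2 (-0.66, SE 0.25) and Ror2 (-0.80, SE 0.30) were lower and Fzd8 (0.49, SE 0.19) and Ror1 (0.46, SE 0.17) higher in the null arrays, each with an unadjusted limma p under 0.05 and an adjusted p of 0.151 over the list alone. Ndp, the gene of the ligand Norrin, had the same adjusted p but read 3.48 in wild type and 2.88 in the null arrays, about and below the arrays' lower quartiles. Of 26 members 0 passed, and fry for change in either direction gave adjusted p = 0.0285 for the list. Across all genes, 52 had an unadjusted p under 0.001 where 18.2 would by chance, while 1736 had groups that did not overlap, 9.54% against 10% by chance.

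The tests below were chosen after the results were seen, except the counts over other splits of the arrays. Fenestrated and peripheral vessel genes were higher in the null arrays, and 3 sources in the preparations were tested. Choroid plexus tissue in the null preparations would raise epithelial genes, which had a median difference of -1.62. Meningeal vessels with their fibroblasts would raise fibroblast genes. On null replicates 1 and 3 the fibroblast list lay at -2.45 and -0.32 against the wild-type mean, and the fenestrated list at 0.81 and 1.21. On null replicate 2 they lay at 0.473 and 1.27, the former above the fibroblast list's wild-type SD of 0.311. That array does not exclude this source, since the lists' wild-type means differed (9.33 and 7.88) and equal log2 rises need not follow. Higher endothelial purity would raise all endothelial genes alike, yet on each null array the median shift of all fenestrated members lay above that of all pan-endothelial members, by 0.405 at the lowest, against an SD of 0.097 between wild-type arrays. Meningeal vessels stay open for null replicate 2. Open for all null arrays are endothelial cells of such vessels captured without their neighbouring cells, for which no test was run. A response of cerebellar endothelium to the loss of Frizzled4, the hypothesis the genotype offers, is open too.

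Several lists of other cell types had lower group medians in the null arrays, but not all were lower on each null array. On null replicates 2 and 3 the list mean minus the wild-type mean was 0.12 and 0.02 for microglia and 0.27 and 0.10 for astrocytes. It was 0.01 and 0.31 for mural genes and 0.47 and -0.32 for fibroblast genes. A purer null replicate 1 preparation leaves the choroid plexus and platelet lists, 2 of 2 of which stayed lower without that array. Both also stayed past the threshold there, in camera at the preset correlation of 0.01. More choroid plexus in wild-type replicate 3 is not the whole difference, since the choroid plexus median was -0.87 without that array. The list still passed there at the same preset correlation. With all arrays, the estimated correlation was 0.64 for choroid plexus and -0.045 for platelet genes, and camera with it gave adjusted p = 0.517 and 0.344. For choroid plexus genes, passing therefore cannot exclude tissue carried over in amounts that varied between preparations. The microglia, fibroblast, astrocyte and mural differences rest on null replicate 1, where the lists lay at -2.35, -2.45, -1.68 and -1.28. Without that array their medians were 0.10, -0.05, 0.19 and 0.26. Whether a purer preparation lowered them there cannot be told, since 3 of 5 lists of other cells outside the pattern had their lowest mean on that array. Nor can it for Purkinje genes, whose median stayed at -0.29 without null replicate 1 while the call ended. How much choroid plexus each dissection carried stays open, as does a genotype effect on the choroid plexus, platelet and Purkinje lists. For the microglia, astrocyte and mural lists, null replicates 2 and 3 argue against a lowering common to the null arrays. For fibroblast genes those arrays lay on either side of the wild-type mean.

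Genes next to Fzd4 had a low p more often than genes elsewhere. Of the 40 nearest measured genes in the order of assembly GRCm38.p6, 7 had an unadjusted p under 0.05 (17.5%, exact Clopper-Pearson 95% interval 7.34 to 32.8%), against 837 of 18193 genes overall (exact binomial p = 0.00212, one-sided). They were Nox4 (1.10), Stard5 (0.94), Prss23 (0.86) and Rab30 (0.57), higher, and Sytl2 (-1.66), Ctsc (-0.74) and Tmem126b (-0.56), lower, none past the adjusted threshold. Of 17221 overlapping windows of the same size along the genome, 130 (0.755%) held as many. A candidate explanation is a segment of the strain in which Fzd4 was deleted, kept around the gene in the mixed strain background of these mice. Such a segment may change expression or probe binding, and local effects of the deletion itself were not tested. Exoc3l2 lies on the same chromosome as Fzd4, with 630 of the 1413 measured genes there between them. Whether such a segment reaches Exoc3l2 was not tested.

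The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05, and the real split was the only one to call any gene, 4 against 0 at the highest of the others, with the same numbers for at least 2-fold differences, so 1 of 10 splits gave as many in each case. For the fenestrated list, the unadjusted camera value was 5.26e-12 in the real split and 4.07e-05 at the lowest of the others, so 1 of 10 gave as small a value. The number of lists called was 12 in the real split and 12 in another, which put both arrays numbered 3 together, so 2 of 10 gave as many. Among the splits that, like the real one, part all 3 numbered pairs, the others called 3, 10 and 8 lists, and the rest keep a pair together.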
